A study of Boehmeria nivea with 2 samples.

How the data were processed

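Gene expression was measured by sequencing the RNA of roots of ramie (Boehmeria nivea, a perennial fibre crop of the nettle family), cultivar Qingdaye, from plants 30 days old. There were 2 libraries, 1 of roots inoculated with Pratylenchus coffeae, a migratory root-lesion nematode, and 1 of roots given water without nematodes. Per the labels' protocols, each inoculated plant received 150 nematodes, and roots were taken 1, 3 and 5 days later. Roots of 3 plants were pooled at each time point, and RNA of the 3 time points was mixed in equal parts before 1 paired-end library per group was made and sequenced on an Illumina HiSeq 2000. The independent plants were therefore averaged inside each library, and neither the spread between plants nor the time course can be measured from the values.

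Each deposited file lists the same 40826 unigenes, which are assembled transcript sequences with lengths from 201 to 12195 bp (median 421 bp). Per the file headers, it gives the number of reads (a raw count), the number of unique reads, RPKM, the mean read depth and the share of the unigene's length covered. The count of all reads and the count of unique reads held the same number for every unigene in both deposited files, so only 1 of them was used. The RPKM deposited by the authors equalled the reads divided by the unigene length in kilobases and by the read total of the file in units of 1000000, within a tolerance of 1e-09, and carries no scaling beyond the library total. The coverage fraction and the depth signal deposited by the authors are not scaled to library size. The submitters' processing notes name DESeq, with no version. The aligner, the counting program and the reference assembly are not given in the sources used here.

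The files do not pair the unigene IDs with gene names, and no reference was used here. Gene lists (27 of them) that had been written as name patterns before the data were examined could therefore not be applied. By the rule fixed at that time for unnamed IDs, 2 unigenes higher and 2 lower in the infected library are given by ID: those with the largest absolute log2 ratio, with 0.5 reads added to both counts, among unigenes with at least 100 reads over both libraries whose whole interval lay beyond 2-fold. All other results describe groups of unigenes by abundance, length and direction.

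With 1 library per group there is no residual degree of freedom, and no test of infection was made. For each unigene, the ratio of infected to uninfected reads was taken after scaling the library totals with TMM factors (edgeR 4.0.16 in R 4.3.3). TMM changed the ratio of the library sizes by a factor of 0.983. The exact 95% interval of the ratio came from the Clopper-Pearson interval of the infected library's share of the unigene's reads (scipy 1.17.1). These intervals compare 2 libraries, not 2 conditions, and cover only the counting error of independent reads. Copies of 1 molecule made by PCR cannot be told apart here. It is also not known whether the 2 ends of 1 fragment were counted as 2 reads, which would make the intervals too narrow. Among unigenes with at least 10 reads over both libraries, a unigene was listed as higher or lower when its ratio was at least 2 or at most 0.5 and its interval excluded 1. A strict list required the whole interval to lie beyond 2-fold. Log2 ratios were computed with 0.5 reads added to both counts. Where a library had no read, folds were computed against a floor of 3 reads in that library, which corresponds to 0.366 CPM (counts per 1000000 reads) in the uninfected and 0.462 in the infected library. For correlations across unigenes, 1 was added to the scaled CPM before taking log2.

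The listing rule was tested on simulated data in which 200 of the unigenes with at least 10 reads were changed by known folds at the real depths, and 21993 simulated unigenes passed the read minimum. It listed 48% of those changed 2-fold, 80% of those changed 3-fold, 92% of those changed 4-fold and all (100%) of those changed 8-fold, none in the wrong direction. The strict rule took 0%, 50%, 72% and 86% of them. In 20 simulated pairs of libraries with no change and independent reads, the rule listed on average 102 unigenes as higher and 101 as lower, and the strict rule 1 and 0.5.

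Alternatives fixed before the data were examined were scaling by library totals, by DESeq2 1.42.0 size factors or by upper quartiles, other read minimums, folds of 1.5 and 4, and the deposited RPKM. Removing the relation of the ratio to unigene length, halving the counts before the interval, and thinning the uninfected library to the infected total were added after seeing the data. No paired analysis was possible because each group has 1 library.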

Results

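The transcriptome of roots of the ramie cultivar Qingdaye was compared between a pool of plants inoculated with the root-lesion nematode Pratylenchus coffeae and a pool of uninoculated plants, to find genes that respond early to the nematode. Each group was represented by 1 library mixed from roots taken 1, 3 and 5 days after inoculation, so there were no replicates. The uninfected library held 8206312 reads assigned to unigenes and the infected library 6489428, a ratio of 1.26. Of the 40826 unigenes, 28910 had reads in both libraries and 4812 had none in either. At least 1 read was found for 33727 unigenes in the uninfected and 31197 in the infected library, and for 32700 in the uninfected library after thinning it to the infected total. The deposited RPKM was at least 10 for 11308 unigenes in the uninfected and 11381 in the infected library, and at least 100 for 1188 and 1200 unigenes.

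The abundance profiles of the 2 root libraries were alike as a whole. Across the 36014 unigenes with a read in either library, Pearson's r of the log2 scaled counts per 1000000 reads (CPM) was 0.98 and Spearman's rho was 0.91, across unigenes that are not independent replicates. The same unigene was the most abundant in both, with 1.08% of uninfected and 1.19% of infected reads. The 10 most abundant unigenes of each library took 3.79% and 4.53% of its reads, and the 100 most abundant took 13.7% and 14.8%. Of the 3611 unigenes with at least 1000 reads over both libraries, 92.9% differed by less than 1.5-fold and 98.3% by less than 2-fold.

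Unigenes that differed between infected and uninfected roots went in both directions and were mostly of low abundance. Among 21822 unigenes with at least 10 reads, which held 99.6% of uninfected and 99.7% of infected reads, 1010 were at least 2-fold higher in the infected library and 847 at least 2-fold lower, with intervals that excluded equality. The remaining 19965 (91.5%) were not listed. The strict list, with the whole interval beyond 2-fold, held 313 higher and 209 lower unigenes, among them 20 pairs with neighbouring IDs and the same direction. Unigenes with fewer than 100 reads over both libraries made up 77.8% of the higher and 83.4% of the lower list. The higher list took 1.1% of uninfected and 3.6% of infected reads, and the lower list 0.925% and 0.349%. Halving the counts before the interval, as if every read were present 2 times, left 563 higher and 406 lower unigenes (168 and 82 on the strict list). With every read present 2 times, no change and the counts not halved, simulated libraries gave on average 560 higher and 543 lower (51 and 58 on the strict list). Copying of this amount would put both reads of every unigene with exactly 2 reads on the same bases. That was seen in 16.5% of such unigenes in the uninfected and 26.8% in the infected library. How much of the 1010 and 847 copied reads could give is therefore not known. More lower than higher unigenes were listed with the relation of the ratio to unigene length removed (833 higher and 1026 lower) and from the deposited RPKM with a pseudocount of 1 (2584 and 2790). The strict list still held more higher unigenes with the length relation removed (264 higher and 246 lower), but as many of both at 4-fold (59 and 59).

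**Figure D1:**
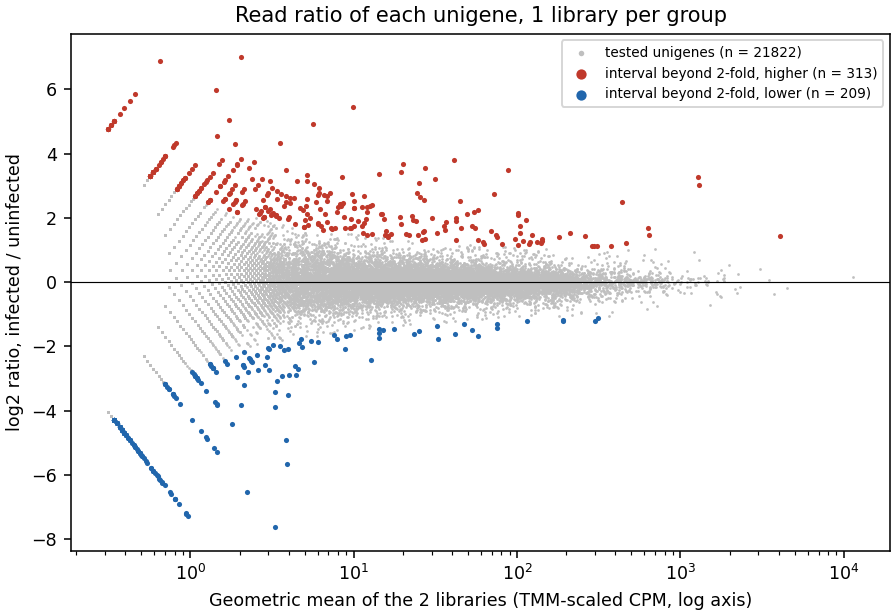
Each point is 1 of 21822 unigenes. The x axis is the geometric mean of its TMM-scaled CPM in the 2 libraries (log axis) and the y axis its log2 ratio of infected to uninfected reads, both with 0.5 reads added to each count. Red and blue mark the 313 higher and 209 lower unigenes whose whole 95% counting interval lay beyond 2-fold, and the diagonal rows at the left are unigenes with the same small read number in 1 library.

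Among abundant transcripts, more unigenes were higher than lower in infected roots. Of the 3611 unigenes with at least 1000 reads, 44 were listed as higher and 19 as lower, and 37 and 8 were on the strict list. The higher ones had a median fold of 2.6 and a maximum of 14-fold, and together took 0.813% of uninfected and 2.7% of infected reads. The lower ones had a median fold of 2.17 and a maximum of 3.2-fold. Among the 120 unigenes with at least 10000 reads, 6 were higher, by a median of 2.99-fold and at most 9.59-fold, and 0 were lower. These 6 alone accounted for 0.461% of uninfected and 1.74% of infected reads. The excess of higher unigenes at 1000 reads or more was also seen after the length relation was removed (41 higher and 16 lower).

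Among unigenes with 100 to 999 reads, 180 of 9488 were higher by a median of 2.8-fold, and 122 were lower by a median of 2.36-fold. Below 100 reads, 786 of 8723 were higher and 706 lower, with median folds of 3.86 and 3.89 among those with reads in both libraries. With few reads, the interval excludes 1 only at larger ratios. The median folds of listed unigenes therefore cannot be compared between read classes. Reads stacked on the same bases were more frequent in the infected library, in 26.8% of its unigenes with exactly 2 reads against 16.5% in the uninfected library. In unigenes with 10 to 29 reads, the interquartile range of the log2 ratios was 1.53, against 1.08 expected from counting independent reads and 1.53 with every read present 2 times. In those with 1000 to 2999 reads it was 0.33 against 0.10 and 0.14. Without replicates, this spread cannot be divided into copied reads, fragments counted by both ends, and variation between plants, between library preparations and between conditions. The expected ranges were normal approximations from the median counting error, not simulations, and are rough at few reads.

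**Figure D2:**
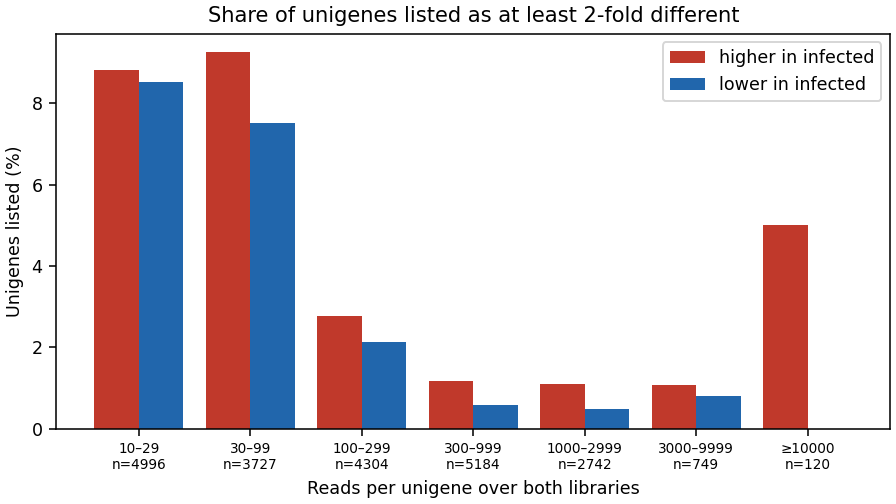
Bars give the percent of unigenes listed as at least 2-fold higher (red) or lower (blue) in the infected library, by the number of reads per unigene over both libraries, with n the unigenes tested in each class. The share listed as higher is 8.83% at 10 to 29 reads and 1.09% at 1000 to 2999 reads, and the 120 unigenes with at least 10000 reads include 6 higher and 0 lower.

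Among unigenes of the strict list with at least 100 reads over both libraries, T1_Unigene_BMK.4169 (556 bp) had the highest log2 ratio (0.5 reads added). It had 1 uninfected and 149 infected reads. Its deposited RPKM was 0.219 and 41.3, and its ratio was 192-fold with a 95% counting interval from 33.9 to 7623. It was followed by T1_Unigene_BMK.5469 (872 bp), with 12 and 419 reads and an RPKM of 1.68 and 74.0. This ratio was 44.9-fold, with an interval from 25.5 to 87.7, and infected reads covered 100% of its length.

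Among unigenes of the strict list with at least 100 reads over both libraries, T1_Unigene_BMK.22366 (1027 bp) had the lowest log2 ratio (0.5 reads added). It had 380 uninfected reads and 1 infected read. Its RPKM was 45.1 and 0.15, and it was 295-fold lower in the infected library, with a 95% counting interval from 52.7 to 11694. T1_Unigene_BMK.21794 (1272 bp) came next, with 100 uninfected reads, an RPKM of 9.58, and 0 infected reads. Taking 3 reads as the floor in the infected library, it was 25.9-fold lower there, and its 95% counting interval reached down to 20.7-fold. Ranked by that floor in place of the added 0.5 reads, it would come 5th among the lower unigenes of the strict list with at least 100 reads. Uninfected reads covered 97.1% of the length of T1_Unigene_BMK.22366 and 93.9% of T1_Unigene_BMK.21794.

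Transcripts found in only 1 of the libraries were more frequent in the uninfected roots. There were 134 unigenes with at least 10 uninfected and 0 infected reads, and 18 with at least 10 infected and 0 uninfected reads. The 134 had a median length of 648 bp and a median of 15 reads, and took 353 CPM of the uninfected library. The 18 had a median length of 334.5 bp and a median of 12 reads, and took 39.9 CPM of the infected library. With the uninfected library thinned to the infected total the counts were 91 and 36, a narrower gap. In simulated libraries with no change and independent reads, on average 2.5 unigenes were found only in the uninfected and 0.25 only in the infected library. With every read present 2 times and no change, the averages were 110 (at most 144) and 28.9 (at most 35). The observed 134 lay between that average and maximum, and the observed 18 below its average, with no minimum recorded. Copying of this amount would stack both reads of every unigene with exactly 2 reads. That was seen in 16.5% of such unigenes in the uninfected and 26.8% in the infected library. How many of the 134 and 18 copied reads could give is therefore not known. At a minimum of 20 reads the counts were 40 and 2. The files do not say which organism a unigene came from. Neither the 18 nor the other unigenes listed as higher can therefore be assigned to the plant or to the nematode. This holds for the 2 higher unigenes given by ID as well.

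Unigenes higher and lower in infected roots differed in length. The 1010 higher unigenes had a median length of 491 bp, the 847 lower ones 717 bp, and the 19965 others 1102 bp. Their median reads over both libraries were 34.5, 29 and 216. Tested unigenes with few reads were shorter, with a median of 446.5 bp at 10 to 29 reads and 1626 bp at 300 to 999. The gap to the others was therefore not separated from abundance. Below 300 bp, 156 unigenes were higher and 48 lower. From 1000 to 1999 bp, 112 were higher and 212 lower, and from 2000 to 3999 bp 15 were higher and 45 lower. A relation to length was also seen across all well-measured unigenes, listed or not. Among the 8795 unigenes with at least 300 reads, Spearman's rho of length and log2 ratio was -0.33 across unigenes. Their median log2 ratio was 0.07 in the 127 unigenes of 200 to 499 bp, 0.12 at 500 to 999 bp, -0.05 at 2000 to 2999 bp and -0.24 at 4000 bp or more. In the longest class, 84.8% of 442 unigenes had a log2 ratio below 0, against 33.3% of 1161 at 500 to 999 bp.

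**Figure D3:**
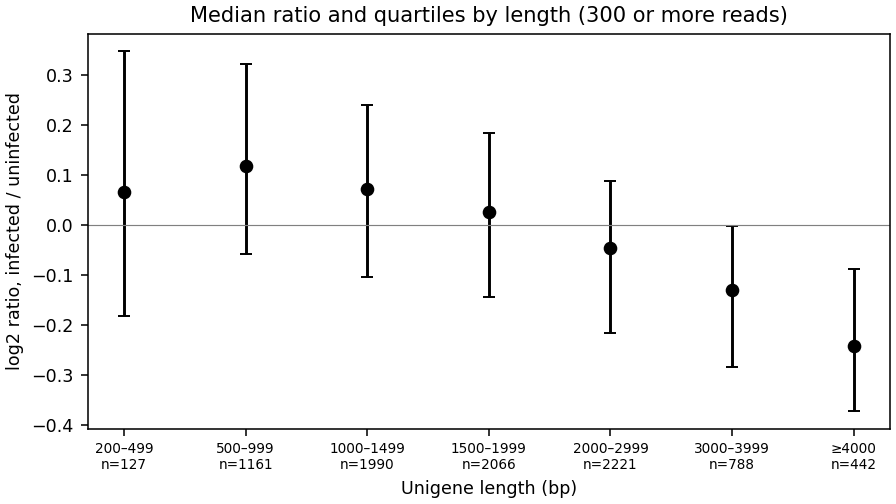
Points are the median log2 ratio of infected to uninfected reads of unigenes with at least 300 reads, by unigene length in bp, and bars span the lower to the upper quartile. The median is 0.07 at 200 to 499 bp, then declines from 0.12 at 500 to 999 bp to -0.24 at 4000 bp or more.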

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

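All tests in this part were chosen after the values were seen. The coverage values, which the comparisons of read counts do not use, showed reads stacked on the same bases more often in the infected than in the uninfected library. Of 2604 unigenes with exactly 2 infected reads, both reads lay within the same 101 bases, 1 read length, in 26.8% (95% Clopper-Pearson interval 25.1 to 28.5%). In the uninfected library it was 16.5% of 3049 (15.2 to 17.9%). Reads all 101 bases long with random starts would give 0.522% in the infected and 0.554% in the uninfected library. Shorter aligned reads and the 2 ends of 1 fragment would give more, so the excess over these values does not measure copying.

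Unigene length did not account for the difference in stacked reads, and the number of assigned reads went the other way. Reweighting the infected share to the uninfected length classes gave 27.7%. The infected library had fewer reads assigned to unigenes, with the uninfected total 1.26 times as large. Sequenced depth and aligned read length were not compared between the libraries. Stacked reads may be copies of 1 molecule or both ends of a very short fragment. Copies concentrated in the listed unigenes were not seen at 8 to 40 reads, where coverage was compared with other unigenes of like reads and length. The covered share of length was 1.47 percentage points higher for the higher list (bootstrap 95% interval 0.426 to 2.14). For the lower list it was 1.23 points higher (0.0142 to 2.26). The matching was by broad classes, so shorter length or more reads within a class could hide copies. Copying of all reads alike stays open as a source of part of both lists. Halving the counts before the interval left 563 higher and 406 lower unigenes. A simulation without any change and with every read present 2 times listed on average 560 and 543. Those counts were not halved, so they compare with the 1010 and 847 of the main lists and not with the 563 and 406. That simulation also stacks more reads than were seen. Whether the 2 libraries differed in the amount of starting RNA or in amplification stays open, and no biological explanation was tested.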

How the results depend on the processing

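The 3 other scalings left all 4 list counts within 1.5 times, moved the median log2 ratio by at most 0.03, and moved the share of higher unigenes among those listed (54.4%) to 52.8% at the lowest. The 16 alternative log2 ratios of the unigenes given by ID stayed within their intervals. Removing the length relation, a choice made after seeing the data, left each count within 1.5 times but turned the split to 44.8% higher (strict list 264 and 246, 51.8% higher); 831 of the 1010 higher and 836 of the 847 lower unigenes remained listed. Fewer unigenes were listed as higher and lower (strict lists second) with a minimum of 50 reads (370 and 268; 188 and 76), at 4-fold (442 and 430; 59 and 59), and with counts halved before the interval, also chosen after seeing the data (563 and 406; 168 and 82). More were listed at 1.5-fold (1626 and 1468; 615 and 501) and from the deposited RPKM with a pseudocount of 1, which has no interval and hence no strict list (2584 and 2790, so more lower than higher). Without a read minimum, 1249 were higher and 1020 lower. Unigenes found only in the infected or only in the uninfected library numbered 197 and 639 at a minimum of 5 reads and 2 and 40 at 20 reads, and thinning the uninfected library gave 36 for the infected one. Spearman's rho was 0.96 with a minimum of 10 reads, which removes unigenes near 0. Unique reads equalled all reads, and gene lists could not be applied, so those alternatives were not run. Depth limits the lists at low abundance: of simulated 4-fold changes, 64.5% were listed at 10 to 29 reads, 99.5% at 30 to 99 and 100% at 100 reads or more (strict list 18%, 62% and 98.5%).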

Other observations

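All tests in this part were chosen after the values were seen, except the minimum of 20 reads, which was fixed before. Some unigenes of low abundance had reads over most of their length in the uninfected library and no read in the infected library. There were 40 with at least 20 uninfected and 0 infected reads (median 36 and maximum 100 reads, median length 911.5 bp). Reads covered a median of 92.8% of their length. With at least 20 infected and 0 uninfected reads there were 2 unigenes.

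The length relation does not reach such ratios: the trend fitted to remove it had a most negative log2 value of -0.21, and the median log2 ratio at 4000 bp or more was -0.24. Copies concentrated in the 40 unigenes were not seen. Their covered share of length differed from that of others with like reads and length by 1.58 percentage points (bootstrap 95% interval -0.302 to 4.09). The matching was again by broad classes of reads and length. Copying of every read 2 times fell short of the 40: 20 simulated pairs without any change gave at most 5 such unigenes (mean 2.35). That amount would also stack both reads of every unigene with exactly 2 reads, against 16.5% in the uninfected library. Other amounts of copying, and copying that differs between molecules, were not simulated and stay open. A candidate explanation is RNA of another organism in the uninfected roots, which predicts a separate group of ratios over 32-fold. With 3 reads as the floor this needs 124 uninfected reads, which 0 of the 40 have; of 10049 unigenes with as many, 4 were over 32-fold lower and 0 between 8-fold and 32-fold, too few to decide, so this, a transcript of only some pooled plants and one shut off after inoculation all stay open.

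The lower ratio of long unigenes was not a relation to abundance under another name. Within 5 equal classes of reads per base, the correlation of length and log2 ratio was between -0.34 and -0.24. A candidate explanation is less even recovery along long RNA in the infected library, for example from more fragmented RNA: at 2 to 4 read bases per base, the covered share of the length expected from random reads differed (infected minus uninfected) by -3.12 percentage points at 2000 bp or more and by -1.22 points at 500 to 999 bp. The long class lay further below, by -1.9 points (bootstrap 95% interval -3.79 to -0.469). Stacked reads lower coverage too and were not separated from this, and a response of long transcripts to infection was not tested.

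Neighbouring unigene IDs appeared together on the strict list in the same direction more often than after shuffling. Of 17839 neighbouring pairs, 20 were both on the list in the same direction (16 higher and 4 lower) and 3 in opposite directions. Shuffling within blocks of 1000 unigenes gave 5.54 pairs of the same direction on average and 15 at most (permutation p = 0.0001, one-sided, the smallest that 10000 shuffles can give).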
